A study of Mus musculus with 179 samples.

How the data were processed

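Polyadenylated RNA was measured in 179 single cells of newborn mice. The labels place 99 cells in the meninges at P0 (the day of birth), and 40, 24 and 16 cells in meninges and cortex at P1, P2 and P3. Per the labels' protocols, P0 meninges were dissociated and cells expressing Pdgfrb, the platelet-derived growth factor receptor beta, were enriched by 1 round of magnetic sorting before single cells were picked. In parallel, DiI, a lipophilic tracer dye, was injected under the arachnoid at P0, and dye-carrying cells of cortex and meninges were sorted by flow cytometry at later times. The same protocol text is attached to every cell, so the route of a given cell is not stated, and age, tissue and probably the route of isolation change together between P0 and the later ages. Cell names begin with the letter A, C or D at P0, with A at P2 and with B at P1 and P3. What the letters stand for is not stated. They were used to describe spread, in the rule for named genes, and to compare cells within or between letters, but not as replicates.

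The submitters' processing notes list bcl2fastq 2.17.1.14, STAR 2.5.2a, RSEM 1.2.30, edgeR without a version, and the mouse build mm10, with no role or order. The annotation release and any filter on genes or cells are not given in the sources used here. The deposited TPM values give the share of each gene in the transcripts of a cell, scaled so that all genes sum to 1000000, and they are the unit used here unless another is named. The deposited FPKM values are fragment numbers divided by transcript length and by the total of each cell, and within a cell they stand in a constant ratio to the TPM. The deposited TMM-scaled values were treated as a signal, since they equal the TPM multiplied by 1 factor per cell. All 3 tables hold 47729 gene identifiers, of which 47224 have a symbol and 26056 are at 0 in every cell. Listed TPM values sum to about 1000000 in most cells. In the 44 cells of letter D they sum to between 235819 and 670751, so a median of 51.8% of the full sum (range 32.9% to 76.4%) belongs to genes that are not listed in those cells. 2 cells of letter A also lie under 900000. If genes were removed after scaling, the values of these cells are on a lower scale by a factor common to all genes of a cell.

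Depth was read from the deposited FPKM. In genes with a single annotated transcript, the low FPKM values of a cell are multiples of what 1 fragment is worth. The smallest depth whose fit came near the best score was taken. This gave a median of 2319647 fragments per cell (2095049 to 2629081 by age and letter). The fit scored above that of jittered values in 178 of 179 cells, and on simulated cells it came within 5% in 20 of 20. At the median depth, 1 fragment in a gene of 2 kb is worth 0.216 FPKM. Counts were not used here, so no count model was applied, and the sources used here name no molecular identifiers. Intervals and floors cover counting error only.

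All cells were kept, and the lowest had 1284 genes at 1 TPM or more. Cells were clustered together in scanpy 1.11.5 (Python 3.11.15, leidenalg 0.10.2, scikit-learn 1.9.0) on log2(TPM + 1), with the 1000 most variable genes among those at 5 TPM or more in at least 5 cells, 10 principal components, 10 neighbours and a Leiden resolution of 1. Each cluster was named by the marker list, out of 16 lists fixed before the data were examined, that it expressed most, and was called by that name with the ending -like if at least 3 markers were detected and its 10 leading genes held no more markers of another class than of its own. The 9 clusters gave 4 classes. On simulated cells of known class, with each gene drawn on its own from the cells of that class, 179 of 179 returned to their class. These classes came from the same clustering, and the draws removed structure within a class. The return therefore does not show that real cells were classed rightly. Of the real cells, 164 of 179 kept their class at a resolution of 0.5 and 120 with classes by markers per cell. Clusters 1, 3, 4, 6, 8 and 9 were macrophage-like. Their 10 leading genes held 0 markers of their own class and 0 of another, so the check on leading genes decided nothing for them. Their name rests on the marker list, with 21 or more of 25 macrophage markers detected in each. Cluster 4, with 17 of its 20 cells from letter D, was led by the stress and inflammatory genes Hspa1b, Hspa1a, Ptgs2, Cxcl1 and Il1b, and cluster 9, with 5 cells of letter D, held Cxcl10 and Nr4a2 among its leading genes. In the radial glia-like cluster, 5 of the 10 leading genes were radial glia markers and 3 astrocyte markers. No doublet caller was run, and no cell was removed as a doublet. Markers of a second class were counted: 3 of 114 macrophage-like cells held 5 or more of 28 fibroblast markers at 10 TPM, 14 held 5 or more of 37 neuronal markers, and 2 of 34 fibroblast-like and 2 of 15 neuron-like cells held 5 or more of 25 macrophage markers. Of 30 radial glia markers, 5 or more were held by 25 of 114 macrophage-like, 30 of 34 fibroblast-like and 8 of 15 neuron-like cells, and 15 of 16 radial glia-like cells held 5 or more of 37 neuronal markers. Of 14 astrocyte markers, 15 of 16 radial glia-like cells held 5 or more, with a median of 9.5. Of the fibroblast-like cells, 10 held 5 or more of 23 pericyte or smooth muscle markers and 9 held 5 or more of 27 endothelial markers.

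The labels name no animal, so each age is 1 sample of cells. No test between ages was therefore made, no p-value is given, and SDs over cells describe the cells and not animals. A gene was called detected in a cell at 10 TPM or more. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, and a share of 0 is given with the share that 3 cells would make. Expression differences are differences of the mean log2(TPM + 1) over cells, with P1, P2 and P3 weighted equally, for genes detected in at least 25% of the cells of either side. They understate the change of low genes. Because of the incomplete sums of letter D, every difference is given relative to the median compared gene, a choice made after the sums were seen. That median was 0.49 for P1 to P3 against P0 (0.31 with each cell rescaled to 1000000), -0.13 for P3 against P1, 0.56 (0.34 rescaled) within the macrophage-like class and -0.03 (-0.17 rescaled) within the neuron-like class. A fixed list is described by the median difference of its compared members, where at least 3 were compared, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these cells and is not a test.

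The rule for the genes named was fixed before the data were examined, together with the sample groups, the comparisons, the 16 lists of markers and 23 lists of processes, and most alternatives. It takes the 15 largest differences each way for P1 to P3 against P0, among genes whose means in the 3 letters at P0 all lie on one side of the means of P1, P2 and P3. It takes the 10 largest each way for P3 against P1 and within a class, with the markers and up to 4 members of each list. Numbered gene models were named only among the leading 3. Foxc1, Aqp4, Gfap, Rgs5, Pecam1, Sox10, Emx1 and Hba-a1 lie outside that rule and were chosen after their values were seen. Some genes that the rule takes are not reported here. Of 730 list symbols, 3 were not found. Differences within a class were computed for classes with 5 or more cells on each side, which the macrophage-like and neuron-like classes met.

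The comparison was tested on simulated data in which 200 genes were changed. A 4-fold change had the right sign in 94.0% of raised and 97.7% of lowered genes for P1 to P3 against P0 (5547 simulated genes compared), in 86.0% and 92.5% for P3 against P1 (7692 genes), in 98.1% and 97.9% within the macrophage-like class (5695 genes), and in 61.7% and 73.8% within the neuron-like class (8881 genes). A 2-fold change had the right sign less often, in 75.0% of raised and 84.9% of lowered genes for P1 to P3 against P0. The values were 78.7% and 77.1% for P3 against P1, 88.2% and 86.4% within the macrophage-like class, and 60.3% and 59.5% within the neuron-like class. The median measured difference for a simulated log2 change of 2 was 1.05 for P1 to P3 against P0. A difference of mean log2 values is not a fold of mean levels: as a log2 ratio of mean TPM, 23 of the 30 named genes of that comparison and 19 of 20 within the macrophage-like class were smaller in size. Alternatives covered the TMM-scaled values, FPKM, rescaled TPM, pseudocounts of 0.1 and 10, thresholds of 1 and 50 TPM, 500 and 2000 variable genes, resolutions of 0.5 and 2, classes by markers per cell, cells with at least 1000 genes, no filter on low genes, and letters left out. Gene positions were taken from GENCODE release M21 for GRCm38, the assembly that mm10 names, by gene identifier. Computations used pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.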

Results

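Transcriptomes were collected from 179 single cells of newborn mice, 99 from the meninges at P0 and 40, 24 and 16 from meninges and cortex at P1, P2 and P3. The study asked which cells the meninges hold around birth, and whether cells that resemble neural progenitors and neurons are among them and in the underlying cortex on the following days. A median of 4294 genes per cell reached 1 TPM (range 1284 to 7939), with medians of 3850 at P0, 4939.5 at P1, 3452.5 at P2 and 4449.5 at P3. The median depth read from FPKM steps was 2319647 fragments per cell, and the medians by age and by first letter of the cell name lay between 2095049 and 2629081. Each age is 1 sample of cells with no named animals, so the values have no replicate error and no difference between ages was tested.

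The P0 meninges held 4 cell classes. Cells resembling microglia or macrophages made up 57 of 99 (57.6%, 95% interval 47.2% to 67.5%), and all 57 held Csf1r, the receptor for colony-stimulating factor 1 that these cells need to survive (chromosome 18, 61100598 to 61132149). Cells resembling meningeal fibroblasts made up 32 of 99 (32.3%, 23.3% to 42.5%), and 31 of the 32 held Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042). Neuroblast or neuron-like cells made up 7 of 99 (7.07%, 2.89% to 14%), of which 5 held the neuronal tubulin Tubb3 and 3 held doublecortin, Dcx, a microtubule protein of migrating neurons. Radial glia-like cells were 3 of 99 (3.03%, 0.629% to 8.60%), and all 3 held the fatty acid-binding protein Fabp7 and the glutamate transporter Slc1a3, both abundant in radial glia. Of the 3, 1 held the progenitor filament nestin, Nes. The letters of the cell names differed in make-up at P0: fibroblast-like cells were 44.4% of letter A, 15.8% of letter C and 29.5% of letter D, and neuron-like cells 2.78%, 21.1% and 4.55%.

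Fibroblast-like cells were nearly missing after P0, at 1 of 40 cells at P1 (2.5%, 0.0633% to 13.2%), 0 of 24 at P2, which allows up to 12.5%, and 1 of 16 at P3 (6.25%, 0.158% to 30.2%). Radial glia-like cells made up 6 of 40 at P1 (15%, 5.71% to 29.8%), 5 of 24 at P2 (20.8%, 7.13% to 42.2%) and 2 of 16 at P3 (12.5%, 1.55% to 38.3%). Neuron-like cells were 0 of 40 at P1, which allows up to 7.5%, then 4 of 24 at P2 (16.7%, 4.74% to 37.4%) and 4 of 16 at P3 (25%, 7.27% to 52.4%). Macrophage-like cells remained the most frequent class, at 33 of 40 (82.5%, 67.2% to 92.7%), 15 of 24 (62.5%, 40.6% to 81.2%) and 9 of 16 (56.3%, 29.9% to 80.2%). Within letter A, fibroblast-like cells were 44.4% at P0 and 0 of 24 at P2, and radial glia-like cells 0 of 36 at P0, which allows up to 8.33%, and 20.8% at P2. Sorting on Pdgfrb at P0 and on DiI later can set these shares. The counts also depend on how classes were drawn: at a resolution of 0.5 the neuron-like cells joined the radial glia-like cluster, which then held 31 cells, and with each cell placed by its marker scores alone 83 cells were macrophage-like, 21 fibroblast-like, 11 radial glia-like and 6 neuron-like.

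**Figure D1:**
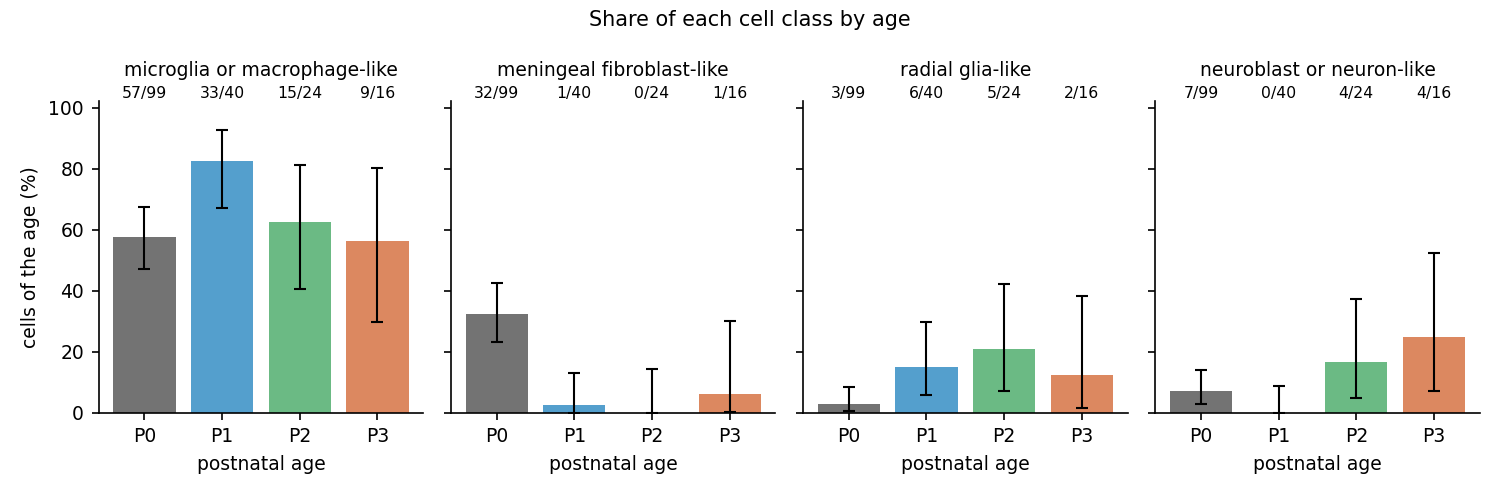
Share of each cell class (percent of the cells of an age, vertical axis) at P0, P1, P2 and P3, with exact 95% binomial intervals as error bars and cell numbers above the bars. Fibroblast-like cells were 32.3% at P0 and 2.5% at P1, and neuron-like cells reached 25% at P3.

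The radial glia-like cells held Fabp7 and Slc1a3 in 16 of 16 cells and Nes in 10 of 16 (62.5%, 35.4% to 84.8%). They also held genes of astrocytes, with 5 or more of 14 astrocyte markers in 15 of 16 cells. The folate enzyme Aldh1l1 was held by 3 of 3 cells at P0 and 12 of 13 later, the water channel Aqp4 by 11 of 16 (68.8%, 41.3% to 89%) and the filament Gfap by 7 of 16 (43.8%, 19.8% to 70.1%). Of the 15 neuron-like cells, 13 held Tubb3 (86.7%, 59.5% to 98.3%), 7 held Dcx, and 5 held Neurod2, a transcription factor of cortical excitatory neurons. Slc1a3 was not restricted to glia, since 29 of 34 fibroblast-like cells held it (85.3%, 68.9% to 95%), at a mean of 389 ± 404 TPM (SD over cells) against 2332 ± 1125 TPM in the radial glia-like cells. Foxc1, a forkhead factor needed for meningeal development, was held by 18 of 34 fibroblast-like cells (52.9%, 35.1% to 70.2%) and by 0 of 16 radial glia-like cells (up to 18.8%), 0 of 15 neuron-like cells (up to 20%) and 0 of 114 macrophage-like cells (up to 2.63%). The endothelial gene Cldn5 was held by 3 of 99 cells at P0 and 1 of 40 at P1, and in 2 fibroblast-like cells, 1 at P0 and 1 at P1, it came with Pecam1, a second endothelial gene. That P1 cell was the 1 fibroblast-like cell of its age, and Col1a1, Pdgfrb and Slc1a3 were listed at 0 in it. Olig1 and Sox10, which mark oligodendrocyte precursors when held together, were both present in 2 neuron-like cells, 1 at P2 and 1 at P3, and in 1 radial glia-like cell at P3.

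Pdgfrb, the receptor on which P0 cells were enriched (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061), was mainly a fibroblast gene among these cells. It was detected in 20 of 34 fibroblast-like cells (58.8%, 40.7% to 75.4%), with a mean of 39.7 ± 51.6 TPM, and in 3 of 16 radial glia-like cells (18.8%, 4.05% to 45.6%), with a mean of 12.6 ± 27.8 TPM. It was detected in 1 of 114 macrophage-like cells (0.877%, 0.0222% to 4.79%) and 0 of 15 neuron-like cells, which allows up to 20%. The 3 radial glia-like cells with Pdgfrb came from the later ages, and 2 of them held Rgs5, a regulator of G protein signalling that is abundant in pericytes. By age, Pdgfrb was detected in 20 of 99 cells at P0 (20.2%, 12.8% to 29.5%), 2 of 40 at P1 (5%, 0.611% to 16.9%), 1 of 24 at P2 (4.17%, 0.105% to 21.1%) and 1 of 16 at P3 (6.25%, 0.158% to 30.2%). The enrichment acts on the protein, and the values are of RNA. Counting only cells at 50 TPM or more, the share was 26.5% of fibroblast-like cells and 8.08% of the P0 cells.

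**Figure D2:**
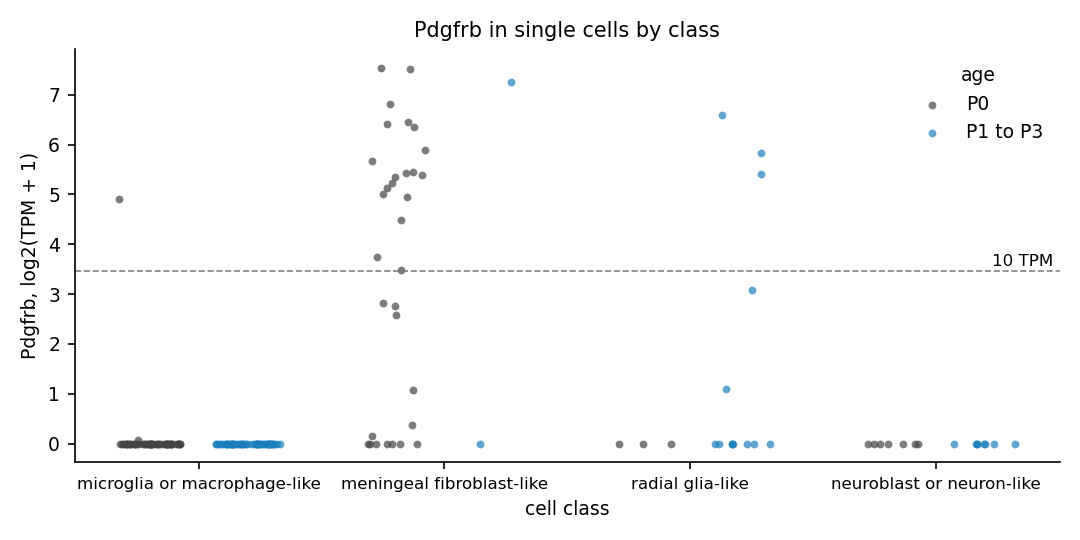
Pdgfrb in single cells, as log2(TPM + 1) on the vertical axis, by cell class on the horizontal axis, with P0 cells in grey and P1 to P3 cells in blue. Each point is 1 cell, spread sideways for visibility, and the dashed line marks 10 TPM, which 20 of 34 fibroblast-like and 1 of 114 macrophage-like cells reached.

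Between P0 and the later ages, all 15 compared fibroblast markers were lower at P1 to P3, and 18 of 25 macrophage markers and 7 of 12 radial glia markers were higher. The largest difference upward was Fabp7 (ENSMUSG00000019874, chromosome 10, 57784881 to 57788450), at 4.59 on the log2 scale, with means of 1.99 ± 3.94 at P0 and 7.08 ± 4.95 later (SD over cells). The tetraspanin Cd9 stood at 4.28. The microglial purine receptors P2ry12 and P2ry13 were higher by 3.33 and 2.73, the lectin Siglech by 3.14 and the receptor Gpr34 by 3.04. Downward, the interferon-induced membrane protein Ifitm2 stood at -5.07 (ENSMUSG00000060591, chromosome 7, 140954837 to 140955987), with means of 8.95 ± 1.71 at P0 and 4.37 ± 4.09 later, and the membrane-binding protein Anxa2 at -4.94.

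Also higher at P1 to P3 were Ighm, the immunoglobulin mu heavy chain (3.64), Rogdi (3.62), the lysosomal arylsulfatase Arsb (3.40), the protease inhibitor Serpine2 (2.96), Ly86, a partner of a Toll-like receptor homologue (2.72), the proton pump subunit Tcirg1 (2.59), the glutamate dehydrogenase Glud1 (2.59) and the neuronal reticulon Rtn1 (2.57). Lower were the chemokine Pf4 (-4.81, chromosome 5, 90772435 to 90773383), Emp3 (-4.55), the growth factor Igf2 (-4.53), the galectin Lgals1 (-4.45), the scavenger receptor Colec12 (-4.37), the apolipoprotein Apod (-4.28), the chemokines Ccl7 (-4.11), Cxcl12 (-4.01) and Cxcl2 (-3.80), decorin, Dcn (-3.81), the hyaluronan receptor Lyve1 (-3.75), and the calcium-binding proteins S100a11 (-4.17) and S100a10 (-3.68). Within letter A, P2 against P0, Cxcl2 stood at -1.89, Lyve1 at -2.46, Tcirg1 at 1.51 and Rtn1 at 3.99. As log2 ratios of mean TPM, 14 of the 30 named genes were smaller by over 1.5 times, among them Fabp7 at 1.44, Rtn1 at 0.61, Serpine2 at 1.04, Pf4 at -1.82 and Lyve1 at -1.38.

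Among the fixed lists, all 15 compared fibroblast markers were lower (median -3.00, percentile 0 among random lists), led by Igf2, Cxcl12 and Dcn, and Col3a1 stood at -3.43. Of the 12 compared collagen and basement membrane genes, 11 were lower (median -2.26, percentile 0). Lists with 3 compared members each gave -2.32 for retinoic acid handling, with the synthesizing enzyme Aldh1a2 at -2.32, and -2.36 for mesenchymal transcription factors, with Zic4 and Tbx18. Of the 25 macrophage markers, 18 were higher and 7 lower (median 0.87, percentile 100), and those that were lower included Pf4, Lyve1 and the clotting factor subunit F13a1 (-3.40). The 12 compared radial glia markers had a median of 0.51 (percentile 99), 7 of them higher, and the 6 neuronal markers 0.75 (percentile 99.4), all higher. The 3 compared astrocyte markers were lower (median -1.35, percentile 1.33), with Gja1 at -3.37 and Sparcl1 at -1.35, but the list stood at 0.08 with no filter on low genes. Fibroblast-like cells, nearly missing after P0, held a median of 4 of 14 astrocyte markers, so the change of make-up can lower this list. That was not tested. Tubulin and growth cone genes had a median of 0.88 (11 members, percentile 100), cholesterol synthesis genes 0.49 (12 members, percentile 99) and interferon response genes -1.31 (3 of 4 lower, percentile 0.510), with Ifitm3 at -3.34. Endothelial markers stood at -0.96 (4 of 5 lower, percentile 1.51), with Ramp2, a receptor partner of adrenomedullin, at -1.77, and Wnt and Bmp signalling genes at -1.19 (3 of 4 lower, percentile 0.54), with the Bmp target Id3 at -1.99. Cell cycle lists lay near the middle, with S phase at -0.04 (14 members, percentile 41.6) and G2 and M phase at 0.23 (3 members, percentile 71). Immediate early genes stood at -0.49 (10 of 18 lower, percentile 1.03), but at 0.08 without the cells of letter D. Without letter D the macrophage list stood at 1.38, and it stood at 0.25 as a log2 ratio of mean TPM.

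**Figure D3:**
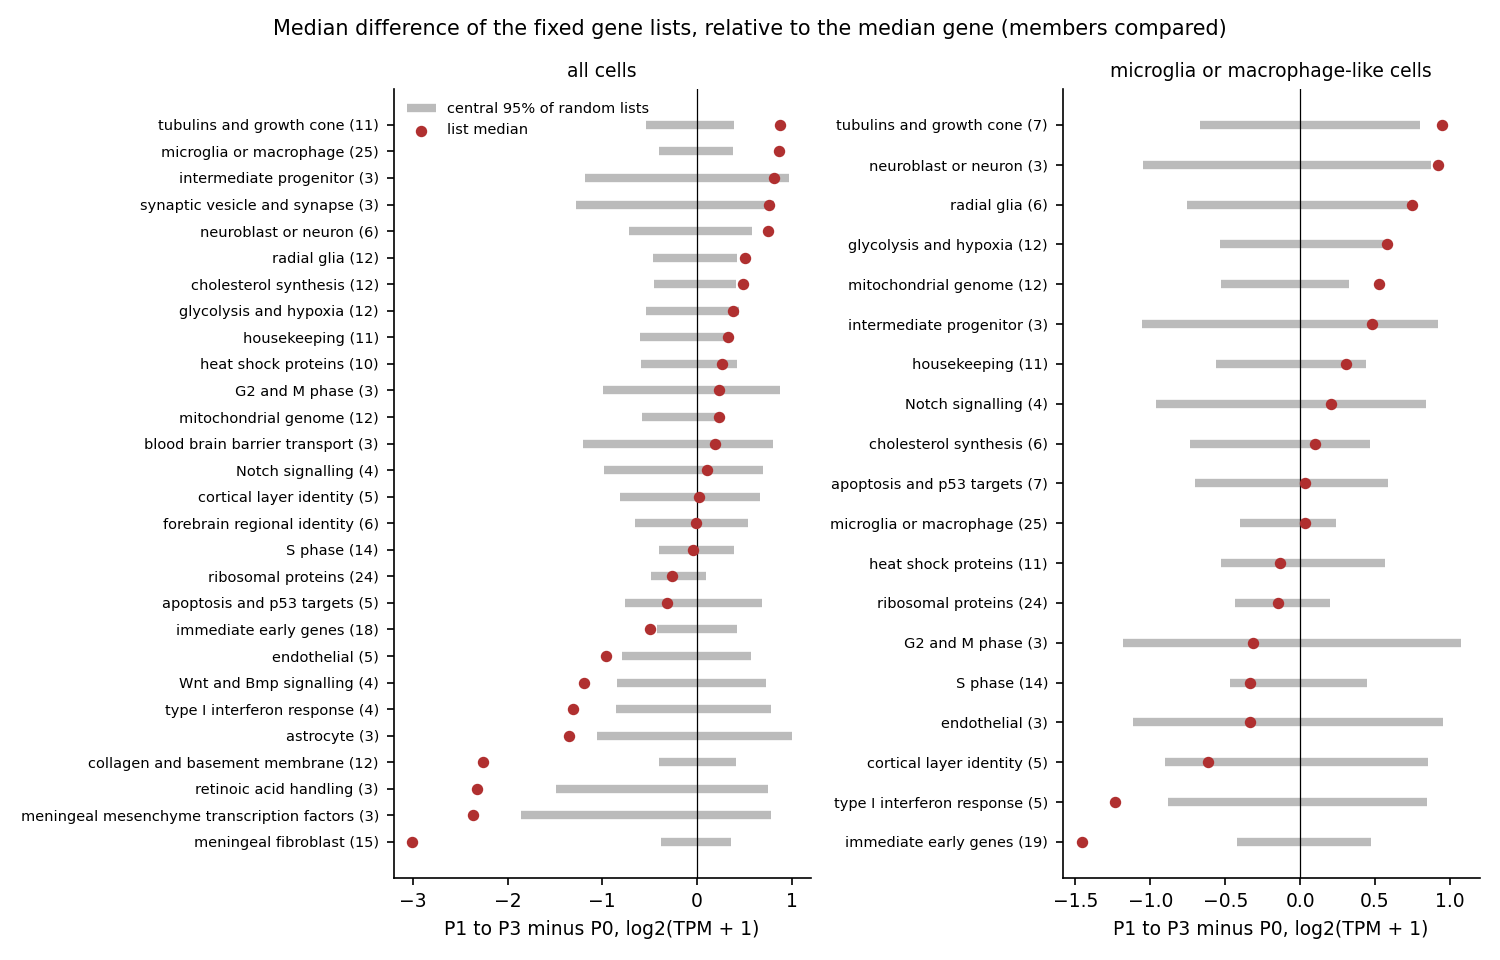
Median difference of each fixed gene list, P1 to P3 minus P0 in log2(TPM + 1) relative to the median gene on the horizontal axis, over all cells and within macrophage-like cells, with the number of compared members in brackets. Red points are list medians and grey bars the central 95% of random lists. Over all cells the fibroblast list stood at -3.00 and the macrophage list at 0.87, and within macrophage-like cells immediate early genes stood at -1.46.

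P3 cells differed from P1 cells, which share the name letter B, by more neuronal and fewer macrophage transcripts. The neuronal markers Mllt11 (3.95), Tubb3 (2.99), Crmp1 (2.72) and the axonal protein Mapt (2.46) were higher at P3, and of 17 compared neuronal markers 16 were higher (median 2.14, percentile 100). Of the 25 macrophage markers 24 were lower (median -2.11, percentile 0, and -0.60 as a log2 ratio of mean TPM), among them Pf4 (-3.22), the signalling adaptor Tyrobp (-3.08) and the complement chain C1qc (-2.76). Neuron-like cells were 0 of 40 at P1 and 4 of 16 at P3, and macrophage-like cells 82.5% and 56.3%, so the 2 ages differ in make-up. Tubulin and growth cone genes, which share Crmp1 and Mapt with the neuronal markers, stood at 1.92 (20 members, percentile 100), synaptic genes at 1.80 (7 members, percentile 100), forebrain regional genes at 1.5 (6 members, percentile 99.9) and S phase genes, all 17 lower, at -1.23 (percentile 0), with the replication helicase subunits Mcm3 at -2.55 and Mcm7 at -2.39.

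Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), had the largest difference upward, 4.96, and was detected in 16 of 16 cells at P3 (lower bound 79.4%) and 7 of 40 at P1 (17.5%, 7.34% to 32.8%). The Y-linked translation factor gene Eif2s3y (chromosome Y, 1010543 to 1028847) had a mean of 4.15 ± 3.41 at P1 and was listed at 0 in every P3 cell. Other named genes that were higher at P3 were the tubulin acetyltransferase Atat1 (3.95), Zfp68 (3.88), Alg2 (3.40), carboxypeptidase E, Cpe (3.37), Tsc22d1 (3.37), the DNA repair factor Paxx (3.34), Mthfd2l (3.20) and the tubulin Tubb4a (3.16). Lower were the actin nucleation subunit Arpc3 (-4.19), the chemokines Ccl2 (-4.06) and Ccl12 (-3.52), the processed pseudogene Gm12191 (-4.05), Elovl1 (-3.90), the tubulin Tuba1c (-3.51), the mitochondrial ribosomal protein gene Mrpl28 (-3.46) and Cnih4 (-3.43). Reads of Gm12191 can be shared with its parent gene, so its value is uncertain. Cpe stood at -0.44 as a log2 ratio of mean TPM, the opposite direction.

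Within the macrophage-like class, 57 cells at P0 and 57 later, the fixed macrophage list had a median of 0.03, with 13 of 25 members higher and 12 lower. Of 2 sets of 10 markers chosen by name after the genes below were seen, all 10 border macrophage markers were lower (median -2.26, percentile 0) and all 6 compared microglia markers higher (median 2.78, percentile 100). A marker scarce at P0 is compared only if enough later cells hold it, so the filter favours a count of higher microglia markers. Pf4 stood at -8.10, with means of 13.13 ± 1.75 at P0 and 5.59 ± 6.23 later, the chemokines Ccl7 and Ccl24 at -6.76 and -6.56, Lyve1 at -6.48 (chromosome 7, 110850607 to 110863239) and F13a1 at -6.01, all genes known from macrophages of the meninges and other tissue borders or from inflammation. Higher later were the matrix protein Sparc at 5.5, the tetraspanin Cd81 at 4.85, Siglech at 4.26 (chromosome 7, 55768178 to 55778925) and P2ry12 at 4.17, genes abundant in microglia of the brain tissue. The remaining named genes were Ighm (5.44), Serpine2 (4.41), Arsb (4.35), Cd9 (4.22) and Plxdc2 (4.14), all higher, and the chemokines Cxcl2 (-6.24), Cxcl1 (-5.73) and Ccl12 (-5.02), the matricellular protein Ccn1 (-5.38) and ficolin A, Fcna (-4.97), all lower. Within letter A, P2 against P0, Cxcl2 stood at -3.87, Cxcl1 at -2.80 and Cd9 at 2.74. As log2 ratios of mean TPM, 9 of the 10 lower named genes were smaller by over 1.5 times: Pf4 stood at -1.80, Lyve1 at -1.47, F13a1 at -1.45, Fcna at -1.71, Ccl24 at -2.15, Ccl12 at -2.27, Ccn1 at -2.94, Ccl7 at -2.99 and Cxcl2 at -4.04. Of the higher ones Cd81 stood at 2.82. Clusters 1, 4, 6 and 9 held most of these cells at P0 and clusters 1, 3 and 8 most of them later.

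At P0, 56 of 57 macrophage-like cells held Lyve1 (98.2%, 90.6% to 100%), and 8 of these also held Siglech. Later, 17 of 57 held Lyve1 alone, 32 held Siglech alone, 2 held both and 6 neither. Lyve1 came with the transcription factor Sall1 in 1 later cell. It came with P2ry12 in 36 of 57 cells at P0 and in 15 of 57 later, but P2ry12 averaged 126 ± 136 TPM in the 17 later cells with Lyve1 alone and 4215 ± 3103 TPM in the 32 with Siglech alone. Mrc1, the mannose receptor, was held by 57 of 57 cells at P0 and 43 of 57 later (75.4%, 62.2% to 85.9%). Pf4 was detected in 57 of 57 at P0 and 26 of 57 later (45.6%, 32.4% to 59.3%), and P2ry12 in 37 of 57 (64.9%, 51.1% to 77.1%) and 52 of 57 (91.2%, 80.7% to 97.1%). The radial glial gene Fabp7 was detected in 14 of 57 macrophage-like cells at P0 (24.6%, 14.1% to 37.8%) and 33 of 57 later (57.9%, 44.1% to 70.9%), at a mean of 161 ± 522 TPM at P0 and 155 ± 247 TPM later, against 23933 ± 7822 TPM in radial glia-like cells of the same ages.

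**Figure D4:**
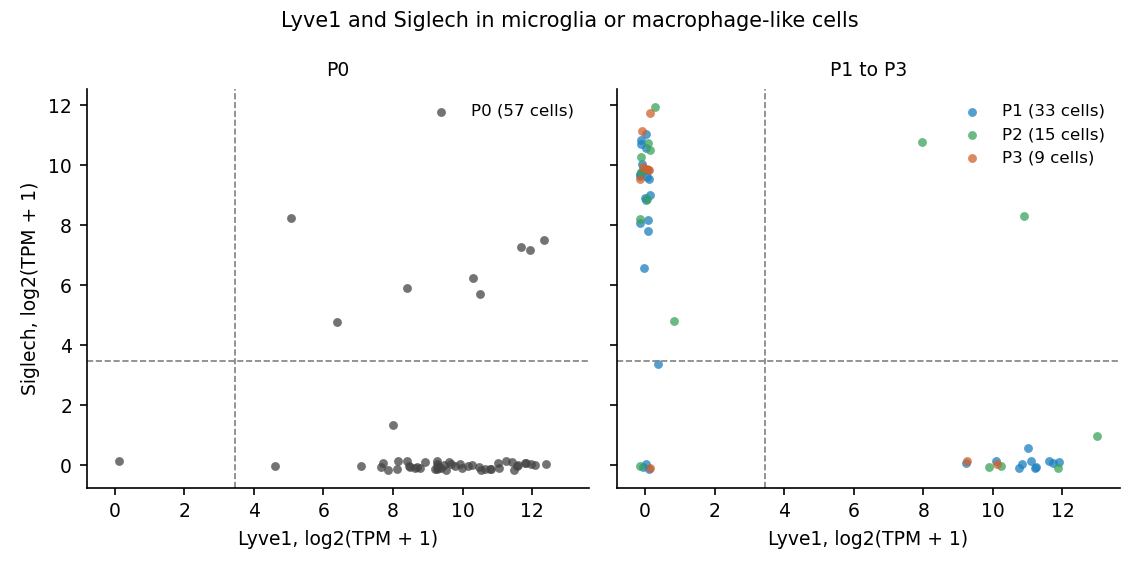
Siglech (vertical axis) against Lyve1 (horizontal axis), each as log2(TPM + 1), in single macrophage-like cells at P0 (57 cells) and at P1 to P3 (57 cells, coloured by age). Each point is 1 cell, jittered slightly, and dashed lines mark 10 TPM. At P0, 48 cells held Lyve1 alone, and later 17 held Lyve1 alone and 32 held Siglech alone.

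Among the lists within this class, immediate early genes, transcribed within minutes of a stimulus, had a median of -1.46, with 17 of 19 lower (percentile 0), including Ccn1, the nuclear receptor Nr4a1 (-3.82) and Ier3 (-3.05). Without letter D the median was -1.09, and within letter A, P2 against P0, it was -0.90. The 5 compared interferon response genes stood at -1.24 (percentile 0.440), with Ifitm3 at -2.56. The mitochondrially encoded genes were all higher, with a median of 0.53 (12 members, percentile 99.7), but at 0.15 without letter D. Glycolysis genes stood at 0.58 (12 members, percentile 97.9) and at -0.05 without letter D, in the opposite direction. S phase genes had a median of -0.33 (14 members, percentile 8.31) and heat shock genes -0.13 (11 members, percentile 19.3). The clusters behind this class differ between P0 and the later ages. Cluster 4, led by stress and inflammatory genes, had 17 of its 20 cells from letter D, and cluster 3 held 0 P0 cells. These medians may therefore mix a change of make-up with a change within cells, which cannot be told apart.

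Within the neuron-like class, 7 cells at P0 and 8 later, 15 of 17 compared radial glia markers and 10 of 12 forebrain regional genes were higher later. Neuronal markers went both ways, with 19 of 34 higher (median 0.57). Fabp7 was higher later by 6.66, detected in 2 of 7 cells at P0 and 8 of 8 later. Zic4 (ENSMUSG00000036972, chromosome 9, 91362413 to 91389348), a zinc finger factor of midline brain regions and meninges, was detected in 4 of 7 cells at P0 (57.1%, 18.4% to 90.1%), with a mean of 319 ± 313 TPM, and was listed at 0 in all 8 later cells, which allows up to 37.5%. Zic1 was likewise detected in 4 of 7 cells at P0 and in none of the later ones. The 1 neuron-like P0 cell of letter A had Zic4 at 0, and no later cell carries letter C or D. Otx2, a patterning gene of forebrain and midbrain, was detected in 4 of 7 at P0 and was at 0 later. The forebrain gene Emx1 was detected in 2 of 7 cells at P0 (28.6%, 3.67% to 71%) and 4 of 8 later (50%, 15.7% to 84.3%).

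Among the lists within the neuron-like class, G2 and M phase genes stood at 2.07, with 19 of 20 higher later (percentile 100). A gene scarce at P0 is compared only if enough later cells hold it, so the filter favours that count of higher genes. The cycling marker Mki67 was detected in 0 of 7 cells at P0 and 2 of 8 later. The list median therefore does not show a rise across the class, and how many later cells carry it was not tested. Axon guidance genes stood at 2.16, with 9 of 13 higher (percentile 100, but 0.27 with no filter on low genes), among them Epha4 (4.53) and Nrp1 (3.18). Forebrain regional genes stood at 1.61 (12 members, percentile 99.8). Cortical layer genes stood at 1.19 (15 members, percentile 98.8) and radial glia markers at 1.35, with 15 of 17 higher (percentile 99.8). Lower later were markers of Cajal-Retzius cells, early neurons of the cortical surface, at -2.36 (3 members, percentile 0.6), with Reln at -1.85 and Calb2 at -2.36. Apoptosis and p53 targets stood at -1.94 (5 of 8 lower and 3 higher, percentile 0.190), with Bax at -5.38 and Bbc3 at -3.05. Oligodendrocyte precursor markers stood at 2.43 (5 of 7 higher), and at 0.66 without the 2 cells that held both Olig1 and Sox10. Without those cells the radial glia markers stood at 0.62 and the G2 and M phase genes at 2.82.

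Among the other genes named in this class, those higher later were Lancl2 (5.49), the non-coding gene Gm3764 (5.16), the helix-loop-helix inhibitor Id2 (5.13), the deadenylase complex subunit Cnot2 (4.99), Jakmip2 (4.94), the cyclin Ccnl2 (4.92) and Txndc12 (4.92), while the kinase gene Mapk8 and the mitochondrial import gene Timm22 were listed at 0 in all 7 P0 cells. Lower were Ifitm2 (-5.81), Ciapin1 (-5.44), Ndufs6 (-5.40), Tpm3-rs7 (-5.40), Ankrd10 (-5.39), Pdlim7 (-5.12) and Zcchc17 (-5.06), and the ribonuclease P subunit gene Pop7 was listed at 0 in all 8 later cells. With 7 and 8 cells, 61.7% of simulated genes raised 4-fold had the right sign (8881 genes compared), so the direction of a single gene in this class is uncertain.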

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

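Alternatives set before the data were examined were joined, after the data were seen, by rescaled TPM, uncentred differences, cells taken out by Cldn5 or by Olig1 with Sox10 and, within classes, letter D left out and letter A alone. For the class shares, the Pdgfrb shares and the main lists, 229 alternative values stayed within the 95% interval or the SD over the 3 letters at P0, and 25 moved. For single genes and other lists 1679 stayed, 372 moved and 11 turned direction. Where no reason is given, the cause was not tested. A minimum of 1000 genes per cell removed no cell and so tested nothing. No paired analysis was possible because the labels give no replicate that ages share. At the median depth, 1 fragment in a 2-kb gene was worth 0.216 FPKM, well below the 10 TPM that counted as detected. Sequencing depth alone is therefore unlikely to set the shares near 0, and what does was not tested.

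With cells classed by markers per cell, macrophage-like shares were 34.3% at P0 and 65% at P1, fibroblast-like shares 20.2% and 0%, the radial glia-like share at P3 0%, the neuron-like share at P0 1.01%, and 0% of macrophage-like cells held Pdgfrb. At a resolution of 0.5 the neuron-like cluster was merged, so radial glia-like cells made 10.1% of P0 and neuron-like cells 0% of P0, P2 and P3. The fibroblast-like share at P1, 1 cell, was 0% with 500 variable genes and 0% with endothelial and oligodendrocyte precursor cells taken out, since that cell held Cldn5. When 50 TPM counted as detected, a stricter threshold, Pdgfrb was held by 26.5% of fibroblast-like and 0% of macrophage-like cells, 8.08% of P0 and 0% of P2.

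The macrophage list, 0.87 for P1 to P3 against P0, was 1.15 and 0.70 with pseudocounts of 0.1 and 10, 0.25 as a log2 ratio of mean TPM, 0.62 without letter A, 1.38 without letter D, 1.02 within letter A and 1.36 uncentred. The neuron list was 1.56 within letter A.

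For P1 to P3 against P0, immediate early genes turned to 0.0769 without letter D and 0.003 uncentred, and the astrocyte list from -1.35 to 0.0844 with no filter on low genes. Within macrophage-like cells, with no filter on low genes, radial glia turned to -0.46, neuron to -0.55 and tubulin lists to -0.52, as members at or near 0 entered. There the neuron list was -0.55 as a ratio of means, and glycolysis -0.0461 without letter D. Within neuron-like cells, tubulins were -0.15 as a ratio of means and mesenchymal factors turned from negative to 0.0348 with no filter. Cpe, P3 against P1, was -0.44 as a ratio of means.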

Other observations

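The tests on the 20 named macrophage genes, on all macrophage genes with a difference of 2 or more, on letter A cells, on the direction of border macrophage and microglia markers, on Xist and Y-linked genes, on genes matched to Eif2s3y and on fibroblast transcripts were chosen only after the result was seen. A transcript of cycling cells was detected at every age, but in only 1 cell at P3. Mki67, a nuclear protein of proliferating cells, was detected in 6 of 99 cells at P0 (6.06%, 2.26% to 12.7%), 6 of 40 at P1 (15%, 5.71% to 29.8%), 5 of 24 at P2 (20.8%, 7.13% to 42.2%) and 1 of 16 at P3 (6.25%, 0.158% to 30.2%). Of the cells with Mki67, 13 were macrophage-like, 2 radial glia-like, 2 neuron-like and 1 fibroblast-like. Olig1, a transcription factor of the oligodendrocyte lineage, was held by 13 of 16 radial glia-like cells (81.3%, 54.4% to 96%), and Sox10 by 1 of 16.

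Stress genes differed between name letters within P0. In macrophage-like cells, letter D against letter A, immediate early genes stood at 0.66 (19 members) and heat shock genes at 0.89 (6 of 10 above, and 1.39 with cells rescaled to 1000000 TPM) relative to the median gene, with the inducible chaperones Hspa1b at 3.24 and Hspa1a at 3.10 but Hspd1 at -1.91, and Atf3 at 3.02 and Nr4a1 at 1.92. In fibroblast-like cells immediate early genes stood at 1.13 (12 members), with Dusp1 at 2.38 and Egr1 at 2.12, and heat shock genes at -0.63 (8 members), or 0.07 with cells rescaled to 1000000 TPM. The hemoglobin gene Hba-a1 stood at 105652, 72258 and 30177 TPM in 3 P0 cells.

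Within the macrophage-like class, 10 of 10 border macrophage markers were lower and 6 of 6 compared microglia markers higher at the later ages, although the fixed macrophage list had a median of 0.03. The filter favours that microglia count, since a marker scarce at P0 is compared only if enough later cells hold it. A shift of every later cell by a like amount is argued against by a score. It takes the share held of 139 genes lower by 2 or more, less that of 118 genes higher by 2 or more. By it, 18 of 57 later cells (31.6%, 19.9% to 45.2%) lay at or above the lower end of the central 95% of P0 cells. The genes were picked by their difference between these same cells, so the score is not independent of the pattern. Such a choice favours P0 and later cells lying apart. Scaling of the letter D cells is argued against by letter A alone. There the border markers stood at a median of -2.48 (9 of 10 lower) and the microglia markers at 3.20. Both medians lay outside the central 95% of random lists. The later cells may mix border macrophages with microglia or may have moved to differing degrees, and these cannot be told apart. The 20 named genes are the pattern's top genes alone. Of these, 13 later cells held 5 or more of the 10 lower ones without 5 of the higher ones. The reverse held in 38 later cells, while 5 held 5 or more of both and 1 of neither. Lyve1 came with Siglech in 2 later cells, against 11.3 if independent, and with Sall1 in 1, against 10. It came with P2ry12 in 15, against 17.3. By detection of the same 2 sets of 10 markers, not looked at before that test, 40 later cells held 3 or more genes of both sets and 14 only border genes, but the border set was held by 100% of P0 and 94.7% of later cells and so could not separate them. Age, the inclusion of cortex and the route of isolation stay open as untested reasons.

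Shares of cells with Xist and with Y-linked genes differed by age and letter, and only P3 and letter D held 1 kind alone. Xist was held by 7 of 40 cells at P1 and 13 of 24 at P2, and Y-linked genes by 29 and 5. Lower detection of Y-linked genes at P3 is argued against, since of 686 other genes detected at P1 within 5 percentage points of Eif2s3y (62.5% of cells), 0.146% (0.00369% to 0.809%) were held by 0 of 16 P3 cells, as Eif2s3y was. 2 of the 179 cells held both Xist and any of 4 Y-linked genes, which is consistent with animals of different sex, and the same count leaves few cells that could be doublets of the 2 sexes. Xist was held by 25 of 36 P0 cells of letter A, 7 of 19 of letter C and 0 of 44 of letter D (up to 6.82%), and Y-linked genes by 5, 8 and 32 of them. The labels give no sex and name no animal, so age and animal stay confounded.

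In neuron-like cells, 4 of 7 held Zic4 at P0 and 0 of 8 later (up to 37.5%). The mean log2 value of Zic4 at P0 was 0 in the 1 neuron-like cell of letter A, 6.97 in letter C and 4.25 in letter D. No later cell carries letter C or D, so Zic4 is confounded with the name letter. Lower detection is argued against, with a median of 4494 genes per cell against 4406.5 later. RNA of meningeal fibroblasts is argued against, since 0 of the 4 cells with Zic4 held 2 or more of 5 abundant fibroblast transcripts (up to 75%), whose summed level reached at most 0.458% of the mean in fibroblast-like cells, where Zic4 would need at least 73.7% even of the fibroblast-like cell with most Zic4. Cells from the cerebellum, midbrain or diencephalon under the dissected meninges could account for the pattern, but 0 of 7 with 3 or more of 8 granule cell genes (up to 42.9%), with 1 of 3 radial glia-like cells at P0 holding them, and 2 of 7 with 2 or more of 15 regional genes, against 0 of 8 later, are too few. These origins and a difference of age, of name letter or of meningeal cells cannot be told apart.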
